A study of Danio rerio with 4 samples.

How the data were processed

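The series holds 4 samples of zebrafish (Danio rerio) hearts, 2 taken at 52 hours post fertilization (52 hpf) and 2 at 7 days post fertilization (7 dpf). Per the labels, the hearts came from the Tg(myl7:EGFP-Hsa.HRAS)s883 line, in which the promoter of the cardiac myosin light chain gene myl7 drives a membrane-bound green fluorescent protein. Each sample was a pool of 150 isolated hearts, and the labels call a pool a biological sample. The extraction text speaks of 52 hpf hearts for all 4 samples, so the age was taken from the titles and the age field. Total RNA was labelled with cyanine 3 after oligo-dT priming and hybridised to 1-colour Agilent arrays, 1 array per pool, per the labels' protocols.

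The deposited scanner files hold, per the file headers, spot intensities from Agilent Feature Extraction 11.5.1.1 on an array annotated on the Zv9 assembly, and the submitters' processing notes name Agilent Feature Extraction version 11. The processed signal in these files is an intensity on a linear scale, background-subtracted and detrended within each array by that program, per the file headers. The authors also deposited a value table with 1 column per sample. Its values are intensities on a linear scale with the same median of 111.0 in every column, and quantile normalization of the processed signals over the 4 arrays gave the same values for 100% of 60022 probes within 0.001 on the log2 scale. The table was not centred per gene. The steps that made it are not given in the sources used here.

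That comparison also showed that the 2 kinds of file attach the arrays to different samples. Every column of the value table equalled the scanner file recorded for another sample: 52 hpf replicate 1 the file of 52 hpf replicate 2, 52 hpf replicate 2 the file of 7 dpf replicate 1, 7 dpf replicate 1 the file of 7 dpf replicate 2, and 7 dpf replicate 2 the file of 52 hpf replicate 1. Both assignments come from the deposit and the labels do not settle which one is right. The design fixed before the data were examined took the scanner files' assignment as the main one and the value table as an alternative. Both are reported. The genes and gene lists are described by the value table's column labels because a call per gene was made only there, a choice made after seeing the data, and every direction given in this way depends on those labels.

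For the main comparison, control spots (1319 per array) and spots flagged as outliers (14 to 19 per array) were left out, spots of 1 probe were averaged (300 probes had more than 1 spot), and the log2 processed signal was reduced by its 75th percentile on each array. For the value table the log2 of the deposited intensity was used without further scaling. A gene, by the name the files give, was represented by its probe with the highest mean signal over the 4 arrays. A probe was tested where Feature Extraction called it well above background on both arrays of at least 1 age. No spot was saturated. Age was tested with limma 3.58.1 (lmFit and eBayes, without trend) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Differences are 7 dpf minus 52 hpf on the log2 scale, given ± the moderated standard error, with 2 pools per age, so that p-values measure the spread between pools. With 4 arrays, the number of arrays limits the precision. Where a gene was not well above background on either array of an age, the fold is given as at least the bright age's mean over the dim age's mean of, per array, the higher of the lowest well measured signal and the probe's own signal. Probes of closely related genes, such as globins or trypsins, may share labelled RNA.

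The files held 42870 gene names. Of these, 15041 were gene symbols and 21739 were transcript identifiers. Against the reference gene table (assembly GRCz12tu, used for names only), 13245 symbols were current, 1231 were updated through a synonym and 565 had no match. Coordinates are those of the array files on Zv9.

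Before the data were examined, 41 gene lists were fixed, covering heart compartments, metabolism, signalling, stress and the other cell types that dissected hearts can carry. The list of natriuretic genes had fewer than 5 tested members, which left 40. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. The fry test, which asks whether the members of a list move on balance in 1 direction, was run beside it. Counts of members past the test are given over all genes and adjusted over the list alone. Named genes were chosen by a rule also fixed beforehand. It took the 10 largest rises and 10 largest falls among symbols well above background on all 4 arrays, the 4 largest bounds each way, up to 4 members past the test and the brightest member of each list, and always myl7, myh6, vmhc, nppa and nppb. By the value table's labels the rule gave 154 genes, of which 114 passed the test. Brightest members that did not pass and some of the called members are left out of the text. No tested probe was named nppb.

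The steps were tested on simulated data with 2 arrays per group. For the comparison by the value table's labels, with 200 changed genes among 37181, 94.0% of genes changed by 8 on the log2 scale were called, 44.0% of those changed by 4 and 0% of those changed by 2 or by 1. The size of 8 and a set of 4000 changed genes were added after a first run with smaller sizes recovered none. With 4000 changed genes the shares were 99.6%, 97.1%, 66.4% and 4.8%. For the comparison by the scanner files' labels, they were 84%, 2%, 0% and 0% with 200 changed among 37175 and 98.3%, 81.0%, 10.8% and 0.8% with 4000, so few genes changed by 4 or less would be called there if few genes changed. A simulated list shifted by 1 on the log2 scale had a camera adjusted p of 4.55e-42 with the preset correlation and 0.11 with an estimated one by the value table's labels. The estimated version thus had little reach with 4 arrays in that simulation, where genes varied independently of each other. The simulation does not show which version holds where members of a list move together between pools. By the value table's labels some lists did so within an age. The skin and epithelium list differed by a median of 3.63 between the 52 hpf pools, and the intestine and exocrine pancreas list by -1.43 between the 7 dpf pools. For such lists the p-values at the preset correlation may be too small.

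The arrays lay on 2 slides scanned on 2 days, per the file headers, and each slide held 1 array of each age under both assignments. Same-numbered replicates shared a slide in both, so the replicate block and the slide as a block were 1 and the same fit. In this balanced layout the block left every difference unchanged and left fewer degrees of freedom for the spread between pools. A call lost with the block therefore does not by itself show a slide effect. Over all tested genes, the deviations of same-numbered samples from their group means had a correlation of 0.0126 by the value table's labels and -0.5047 by the scanner files' labels. The alternatives were other background corrections, scalings, filters on dim probes, summaries over probes, variance models, thresholds, the block, each array left out, and for the lists the estimated correlation. The normexp background correction added an offset of 50 to the intensities.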

Results

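Gene expression was measured on 4 arrays, each hybridised with RNA from a pool of 150 zebrafish hearts, 2 pools at 52 hpf, when the heart tube has looped, and 2 at 7 dpf, in the early larva. The comparison of the ages asks how the expression of the heart's genes differs between these stages. Array brightness differed by 4.46-fold. By the scanner files' labels the 75th percentile of probe intensity was 152.8 and 343.8 for the 52 hpf replicates and 330.4 and 680.9 for the 7 dpf replicates, and the share of probes well above background was 81.4%, 84.0%, 85.2% and 93.6% in that order.

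The deposited files disagreed on which array belonged to which sample. Each column of the authors' value table had a Spearman correlation of 1 with the scanner file of another sample. With the file of its own sample the correlation was 0.897 and 0.947 for the 52 hpf replicates and 0.873 and 0.959 for the 7 dpf replicates. Over 46023 probes well above background on all arrays, the pairs of pools that share an age by the value table had Pearson correlations of 0.958 and 0.959. The pairs that share an age by the scanner files had 0.897 and 0.888. These are correlations across probes, which are not independent replicates. Both assignments are reported.

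**Figure D1:**
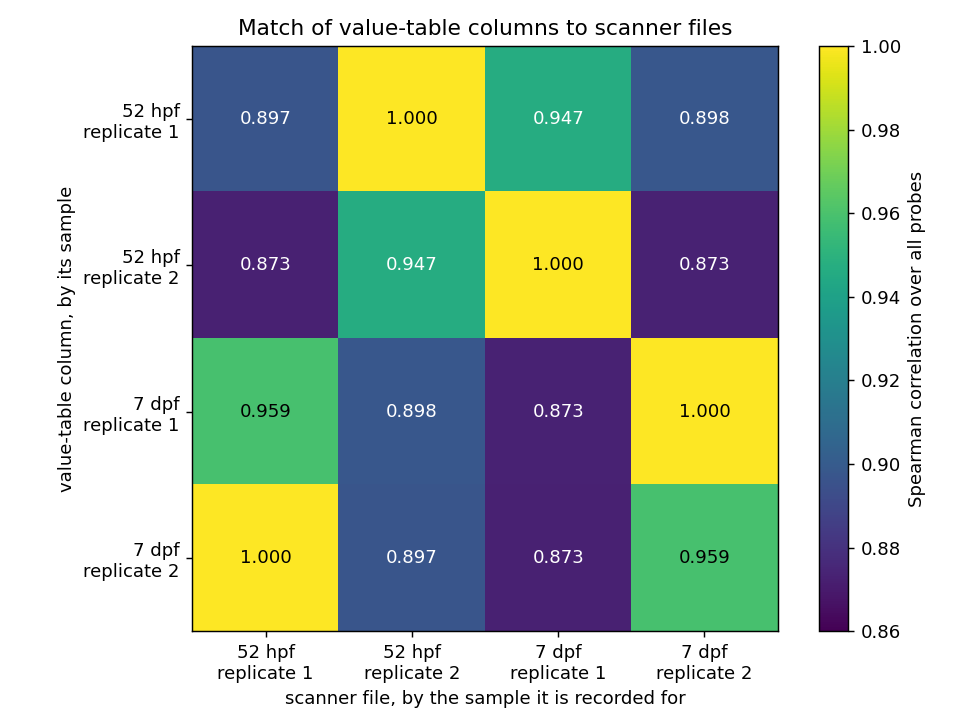
Spearman correlation over all probes of each column of the authors' value table (rows) with each scanner file (columns), both named by the sample they are recorded for. The 4 values of 1 lie off the diagonal, so that no column matches the scanner file of its own sample.

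By the scanner files' labels no gene passed the test among 37175 genes (limma, adjusted p under 0.05), and 583 had an unadjusted p under 0.05. That is fewer than the share of 0.05 that would arise if no gene differed, so the 583 are no sign of an age difference. By the value table's labels 8597 of 37181 genes had an unadjusted limma p under 0.05. The myosin light chain gene myl7 had a difference of -0.56, the atrial myosin heavy chain myh6 -0.80, the ventricular myosin heavy chain vmhc -0.42 and the atrial natriuretic peptide nppa -0.48, each with a limma adjusted p of 1. By camera 14 of 40 lists were shifted. The members of the skin and epithelium list had a median difference of 2.33 (adjusted p = 3.43e-25), those of the retina and lens list 1.09 (9.78e-06) and those of the neural list 1.07 (3.37e-11). Smaller positive medians were found for the lists of liver and plasma proteins (0.71), fibrillar and network collagens (0.40), cell cycle (0.36), gill, ionocyte and cartilage (0.31), retinoic acid and thyroid hormone (0.30) and skeletal muscle (0.09). Negative medians were found for the lists of sarcomere (-0.39), autonomic receptors (-0.36), macrophage (-0.34), oxidative phosphorylation (-0.29) and ribosomal proteins (-0.28). None of these 14 calls held with an estimated correlation (adjusted p between 0.917 and 0.938), and no member of any list passed the test when adjusted over the list alone. By limma's fry none of the 40 lists moved on balance in 1 direction (adjusted p = 0.997 for each). Of the 14 lists only skin and epithelium and neural kept their call whichever array was left out, with medians from 0.94 to 2.94 and from 0.24 to 1.81. Without 7 dpf replicate 2, 143 genes were called higher at 7 dpf.

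By the value table's column labels, 895 of 37181 genes were higher and 628 lower at 7 dpf (limma, adjusted p under 0.05), 421 and 330 of them with a gene symbol. Genes that rose included 34 of 49 of the liver and plasma protein list, 22 of 31 of the intestine and exocrine pancreas list, 10 of 25 of the complement and antigen presentation list and 7 of 20 of the epicardial list, and those that fell included 8 of 90 of the cell cycle list. All 1523 differences were at least 2-fold (smallest 1.54 on the log2 scale), and all had the same direction within both slides. With 2 pools per age, passing the test at this threshold already requires both traits, so neither adds support. On neither 52 hpf array were 336 of the higher genes well above background, and on neither 7 dpf array 83 of the lower ones. The split of higher and lower calls depended on the scaling and the background correction. It was 1068 to 437 when arrays were scaled on probes detected on all 4, where the median of all tested genes was 0.15, and 91 to 2 with normexp background correction and 75th percentile scaling together, against 1029 to 520 with that scaling alone. With the slide as a block 395 genes were higher and 114 lower. Without 7 dpf replicate 1 the counts were 75 and 20, without 7 dpf replicate 2 they were 195 and 26, and without 52 hpf replicate 2 they were 888 and 255. Of the 114 named genes past the test, 58 were called with the slide as a block and 29 with normexp and 75th percentile scaling together, and 19 whichever array was left out, with no change of direction. Those 19 include cox6a2, hbbe3, hapln1a, c3b, c9 and the genes of digestive enzymes and plasma proteins named in the next paragraph, apoa2 excepted.

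The 10 largest rises by the value table's labels, cox6a2 excepted, were in genes of the liver, intestine and exocrine pancreas. This ranking covers only symbols well above background on all 4 arrays. Of the liver and plasma protein genes 34 of 49 tested members rose and none fell (44 and 0 adjusted over the list alone), with a median difference of 6.68, or 5.62 with members at their bound where they had one (camera adjusted p = 6.05e-33, and 0.419 with an estimated correlation). Of those of the intestine and exocrine pancreas list 22 of 31 rose (26 adjusted over the list alone), with a median of 7.66, or 7.38 with bounds (adjusted p = 2.42e-23, and 0.419 with an estimated correlation). The trypsin gene try (current symbol prss1) differed by 11.30 ± 0.58 (limma adjusted p = 0.00701), the chymotrypsinogen gene ctrb1 by 10.21 ± 0.59 and the elastase gene ela2l by 9.56 ± 0.74. The liver fatty acid binding protein fabp10a was at least 2426-fold higher, and the amylase amy2a, which is secreted by acinar cells, at least 659-fold higher. The protease inhibitor serpina1 differed by 9.33 ± 0.49 and the apolipoprotein gene apoa2 by 8.41 ± 0.81, a call lost with the slide as a block (adjusted p = 0.0601). Within the slides the median of the liver list was 7.18 and 5.93 higher, and that of the intestine and pancreas list 7.94 and 6.83. The lists share 0 and 1 members with other lists. All gene groups described from here on come from the same 7 dpf pools. By limma's fry, 7 lists moved on balance in 1 direction (adjusted p between 0.0156 and 0.0294), namely these 2, antigen presentation and complement, epicardium, valve and endocardium, focal adhesion, and Wnt, TGF-beta and BMP signalling.

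The sarcomere list, by the value table's labels, had no member past the test. The myl7 difference was -0.25 ± 0.29 (limma adjusted p = 0.654), turning to 0.05 with scaling on the 75th percentile. The differences were 1.23 ± 0.55 for myh6, -0.88 ± 0.35 for vmhc and -1.33 ± 0.52 for nppa, with adjusted p between 0.218 and 0.268. As a set the 36 sarcomere genes had a median of -0.41 (camera adjusted p = 0.0163, and 0.839 with an estimated correlation), a call lost without 52 hpf replicate 1 (0.610). Among genes of calcium handling and excitability, the calsequestrin gene casq2, whose product stores calcium in the sarcoplasmic reticulum, fell by 1.83 on the log2 scale, and its relative casq1b, known from fast skeletal muscle, rose by 3.27 ± 0.35. With the slide as a block casq1b was called and casq2 was not (adjusted p = 0.0777). The remaining 33 members did not pass, and the list was not shifted (camera adjusted p = 0.292).

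Genes of energy metabolism changed singly rather than as lists. Of the oxidative phosphorylation genes 4 of 85 rose and the list median was -0.13 (camera adjusted p = 0.494). All 4 encode subunits of cytochrome c oxidase. The heart and muscle isoform cox6a2, on Zv9 chromosome 3 from 31191042 to 31193221, differed by 8.11 ± 0.31 (limma adjusted p = 0.00582), a 277-fold rise that was 8.05 and 8.17 within the slides. The isoforms cox8b and cox7a1 differed by 4.24 ± 0.39 and 3.76 ± 0.27, and cox5b2 by 3.32 ± 0.56, called neither with the slide as a block (adjusted p = 0.0828) nor under every scaling. Among creatine kinases and myoglobin, 2 of 11 members rose (camera adjusted p = 0.189). The mitochondrial creatine kinase ckmt2b differed by 6.03 ± 0.48, and gatm, which makes the creatine precursor, by 2.64 ± 0.40. Lipoprotein lipase lpl (current symbol lpla), which frees fatty acids for uptake, differed by 2.53 ± 0.27. It was the only member past the test of 48 in the fatty acid oxidation list (camera adjusted p = 0.272). The pyruvate dehydrogenase kinase gene pdk2 (current symbol pdk2b) differed by 3.12 ± 0.30, 1 of 2 risers among 33 glycolysis genes (camera adjusted p = 0.4998). None of 32 genes of the TCA cycle passed (camera adjusted p = 0.438). With the slide as a block gatm (adjusted p = 0.0758) and lpl (0.0568) were not called.

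**Figure D2:**
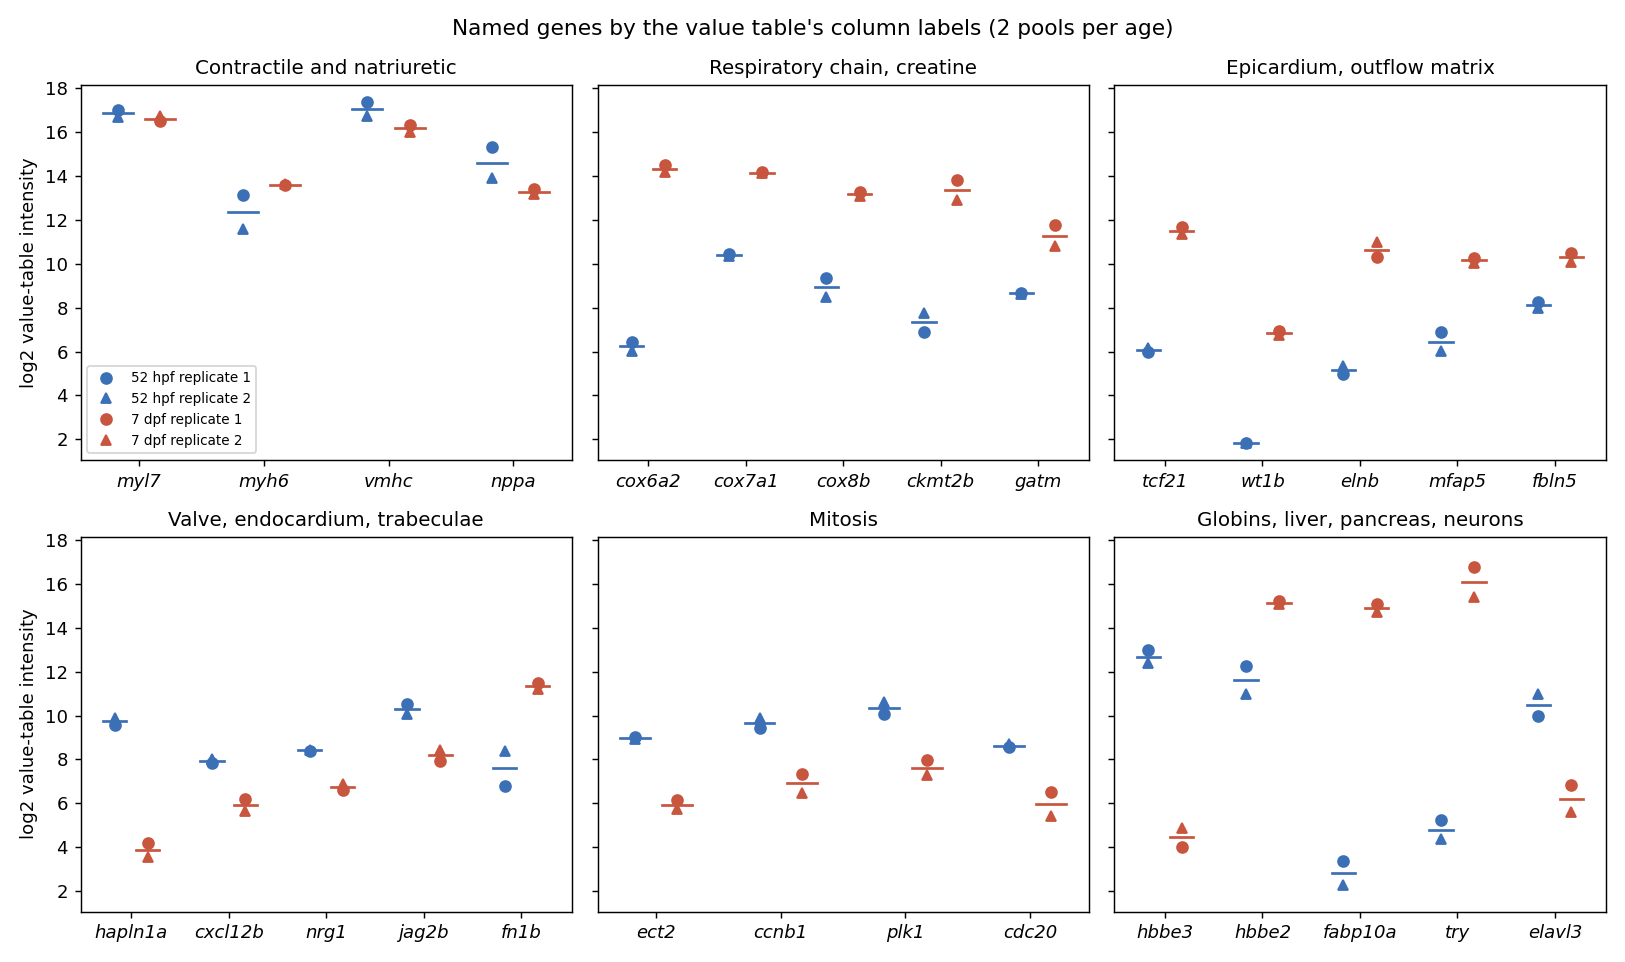
Log2 intensity in the authors' value table (vertical axis) of named genes (horizontal axis) in the 4 pools, grouped by the table's column labels, with circles for replicate 1, triangles for replicate 2 and a bar for the mean of an age. The cytochrome c oxidase gene cox6a2 lies 8.11 higher at 7 dpf on this scale, while the pools of both ages overlap for myl7.

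The epicardial list was higher at 7 dpf by the value table's labels. Of 20 tested members of the list 7 rose and 1 fell (10 and 2 adjusted over the list alone), with a median of 1.22 (camera adjusted p = 8.42e-04, and 0.419 with an estimated correlation). The transcription factor gene tcf21, a marker of the epicardium, differed by 5.42 ± 0.29 (limma adjusted p = 0.00731), a 42.9-fold rise on Zv9 chromosome 23 from 31792848 to 31794275. Another transcription factor gene of epicardial development, wt1b, was at least 9.09-fold higher. The chemokine gene cxcl12a differed by 3.35 ± 0.56, not called with the slide as a block (adjusted p = 0.107), and the orphan receptor gene nr2f1b by -3.75 ± 0.28, well above background on 1 of 2 arrays at 7 dpf. Among 17 genes of outflow tract smooth muscle, 3 rose, namely elnb, which encodes an elastin (5.48 ± 0.36), mfap5 (3.71 ± 0.39) and fbln5 (2.16 ± 0.30), the last not called with the slide as a block (adjusted p = 0.0677). That list was not shifted (7 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.126). Of the matrix remodelling genes 8 of 49 rose and 2 fell (camera adjusted p = 0.0886). Among them were the crosslinking enzyme gene loxl1 (4.63 ± 0.50), the basement membrane gene nid1a (4.21 ± 0.38) and, falling, the tenascin gene tnw, now tnn (-4.57 ± 0.60, well above background on 1 of 2 arrays at 7 dpf). Collagens went both ways, with 1 riser, col6a3 (2.95 ± 0.27), and 3 that fell, col14a1a (-3.10 ± 0.38), col15a1b and col4a6, among 40 (camera adjusted p = 0.126). With the slide as a block loxl1, tnw and the collagens that fell were not called (adjusted p between 0.0601 and 0.0813).

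The lists of valve and endocardium and of cardiac transcription factors were lower by camera, with few members past the test. The 43 genes of the valve and endocardium list had a median of -0.47 (camera adjusted p = 0.022, and 0.477 with an estimated correlation), with 1 riser and 2 that fell (3 and 10 adjusted over the list alone). The hyaluronan link protein gene hapln1a, which acts in cardiac jelly, differed by -5.87 ± 0.35 (limma adjusted p = 0.00911), a 58.4-fold fall, and was well above background on 1 of 2 arrays at 7 dpf. The chemokine gene cxcl12b differed by -1.996 ± 0.33 and the fibronectin gene fn1b by 3.74 ± 0.57. Neither was called with the slide as a block (adjusted p = 0.0912 and 0.0834). Of 33 cardiac transcription factor genes, with a median of -0.47 (camera adjusted p = 0.00104, and 0.729 with an estimated correlation), isl2a (-3.73 ± 0.49, well above background on 1 of 2 arrays at 7 dpf) and irx3a (-2.85 ± 0.45) fell, both lost with the slide as a block (adjusted p = 0.0752 and 0.0565). The neuregulin gene nrg1 and the Notch ligand gene jag2b, which act in trabeculation, differed by -1.66 ± 0.28 and -2.11 ± 0.34. They were the members past the test of 28 in their list (camera adjusted p = 0.791), and neither was called with the slide as a block (adjusted p = 0.0893 and 0.0957). In the list of Wnt, TGF-beta and BMP signalling, with a median of -0.38 (camera adjusted p = 0.0323, and 0.477 with an estimated correlation), lef1 fell by 3.45 on the log2 scale, and bmp2a by 2.16, while the secreted Wnt modulator gene dkk3b rose by 3.10 ± 0.29. Of these, bmp2a and dkk3b were not called with the slide as a block (adjusted p = 0.0681 and 0.0522). Focal adhesion genes had a median of -0.30 with no member past the test (camera adjusted p = 0.0477, 0.526 with an estimated correlation and 0.0530 with the slide as a block). None of 35 endothelial genes passed (camera adjusted p = 0.594). The angiotensin receptor gene agtr2 (2.93 ± 0.34) was the only one of 17 autonomic and related receptor genes past the test (camera adjusted p = 0.0740).

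The cell cycle list was lower at 7 dpf by the value table's labels. Of 90 tested members 8 fell and none rose, and 46 fell when adjusted over the list alone. The median was -1.20 (camera adjusted p = 1.58e-15, and 0.676 with an estimated correlation), or -0.85 and -1.57 within the slides. Among the 8 members past the test, the 4 with the largest falls were genes that act in mitosis and cytokinesis. They were ect2 (-3.04 ± 0.29, limma adjusted p = 0.0146), the cyclin gene ccnb1 (-2.75 ± 0.40), the kinase gene plk1 (-2.72 ± 0.38) and cdc20 (-2.67 ± 0.44). With the slide as a block ect2 was called and the other 3 were not (adjusted p between 0.0858 and 0.0896). The chromatin protein gene hmga1a, from the list of insulin, IGF and growth genes, differed by -2.21 ± 0.31 (0.0801 with the block), and that list was not shifted (camera adjusted p = 0.823). The 87 ribosomal protein genes had a median of 0.28 with no member past the test (camera adjusted p = 8.42e-04, and 0.772 with an estimated correlation).

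The erythroid list was higher, and of its globin genes 1 fell and another rose. In the erythroid list 9 of 28 members rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 1.58 (camera adjusted p = 1.42e-08, and 0.526 with an estimated correlation). The embryonic globin gene hbbe3, on Zv9 chromosome 12 from 21691906 to 21693036, differed by -8.23 ± 0.43 (limma adjusted p = 0.00730), a 300.4-fold fall. Its neighbour hbbe2, from 21702358 to 21703122, differed by 3.53 ± 0.48 in the opposite direction, a call lost with the slide as a block (adjusted p = 0.0628). The biliverdin reductase gene blvrb, the red cell membrane skeleton gene epb41b and the transcription factor gene gata1a differed by 3.37 ± 0.35, 3.12 ± 0.38 and 3.07 ± 0.27. In the thrombocyte list 3 of 12 rose (4 adjusted over the list alone, median 0.94, camera adjusted p = 0.00104, and 0.419 with an estimated correlation). They were gata1a, fn1b and the clotting factor gene f5 (4.29 ± 0.45, well above background on 1 of 2 arrays at 52 hpf). With the slide as a block f5 and fn1b were not called (adjusted p = 0.0595 and 0.0834). Of the 12 members 7 were also in other lists, among them gata1a in the erythroid list and fn1b in the valve and matrix remodelling lists.

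Of the 5 immune lists 4 were higher by camera, and the liver makes complement proteins too. In the list of antigen presentation and complement 10 of 25 members rose (12 adjusted over the list alone), with a median of 1.504 (camera adjusted p = 3.16e-10, and 0.419 with an estimated correlation). The complement genes c9 and c3b (current symbol c3a.2) were at least 131-fold and 51.2-fold higher. Of 29 macrophage genes 4 rose (7 adjusted over the list alone, median 0.86, camera adjusted p = 1.79e-04, and 0.772 with an estimated correlation), among them grn1 (current symbol grna.1), a granulin gene, at least 15.4-fold. In the interferon list 3 of 17 rose (6 adjusted over the list alone, median 0.72, camera adjusted p = 0.00130, and 0.419 with an estimated correlation), with socs1a at 3.63 ± 0.53 and stat2 at 2.15 ± 0.33, both lost with the slide as a block (adjusted p = 0.0752 and 0.0708). The neutrophil list had 5 risers of 17 (5 and 1 lower adjusted over the list alone) and a camera adjusted p of 0.0498, 0.526 with an estimated correlation and 0.103 with the slide as a block. Its largest riser was the carboxypeptidase gene cpa5 (7.66 ± 0.85), which the pancreas list also holds. The next was the complement gene c3a (current symbol c3a.1, 6.40 ± 0.81), which the list of antigen presentation and complement also holds. This gene was well above background on 1 of 2 arrays at 52 hpf and was not called with the slide as a block (limma adjusted p = 0.0758). None of 11 lymphoid genes passed (camera adjusted p = 0.0621).

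The glucocorticoid and circadian list was higher. Of 37 genes in the glucocorticoid and circadian list 6 rose and 1 fell (16 and 3 adjusted over the list alone), with a median of 0.91 (camera adjusted p = 3.55e-05, and 0.676 with an estimated correlation). The clock repressor gene nr1d1 differed by 3.96 ± 0.43 (limma adjusted p = 0.0193), and klf9, a transcription factor gene induced by glucocorticoids and thyroid hormone, by 3.65 ± 0.56. The receptor co-chaperone gene fkbp5 differed by 2.31 ± 0.31, not called with the slide as a block (adjusted p = 0.0757). The time of day of sampling is not given in the sources used here. In the list of retinoic acid and thyroid hormone, the deiodinase gene dio1 (3.00 ± 0.29, 0.0530 with the block) and klf9 were the risers of 25 (camera adjusted p = 0.694). Of 18 hypoxia genes 4 rose (5 adjusted over the list alone, median 0.56, camera adjusted p = 0.0118, and 0.676 with an estimated correlation). They included igfbp1b, which the liver secretes, at least 228-fold higher, and epas1b (2.43 ± 0.27), both lost with the slide as a block (adjusted p = 0.0711 and 0.0595). The list of heat shock and dissociation stress had a median of 0.44 (camera adjusted p = 0.0189, and 0.772 with an estimated correlation), which was not called under 3 other scalings (0.0889 to 0.150). Its 2 risers of 39 (5 and 1 lower adjusted over the list alone) were the transcription factor gene cebpd (4.45 ± 0.50) and the cytokine signalling gene socs3a (1.73 ± 0.27), neither called with the block (adjusted p = 0.0642 and 0.0858).

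Markers of other tissues moved in both directions. The neural list had a median of -1.36 (camera adjusted p = 7.12e-05, and 0.729 with an estimated correlation), or -0.44 and -2.32 within the slides, with 2 of 33 members falling (6 adjusted over the list alone). The neuronal RNA-binding protein gene elavl3 differed by -4.28 ± 0.56 (limma adjusted p = 0.0294, 0.0848 with the block). The 10 largest falls among symbols well above background on all 4 arrays were not tested for a neuronal theme, and held lft2, ppp1r3b, slc35f1 and tfap2e too. Outside the lists they included the Notch ligand gene dla at -4.59 ± 0.32 and the neuronal stathmin gene stmn2b at -4.58 ± 0.64 (0.0845 with the block). The related ligand gene dlb was at least 34.02-fold lower, and otx1a, a brain and eye patterning gene, at least 26.2-fold lower. In the skeletal muscle list 4 members rose and 4 fell of 46 (6 and 7 adjusted over the list alone, camera adjusted p = 0.917). The fast muscle troponin gene tnnc2 (current symbol tnnc2.2) differed by -3.81 ± 0.34, and the calcium buffer gene pvalb1 was at least 10.49-fold higher. In the list of Schwann cells and neural crest, 1 rose and 2 fell of 22, among them the myelin protein gene plp1a (-3.72 ± 0.30, well above background on 1 of 2 arrays at 7 dpf; camera adjusted p = 0.711). No member passed in the lists of skin and epithelium (38 genes, camera adjusted p = 0.651) and retina and lens (16 genes, 0.457). Only hapln1a passed in the list of gill, ionocytes and cartilage (24 genes, 0.307).

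**Figure D3:**
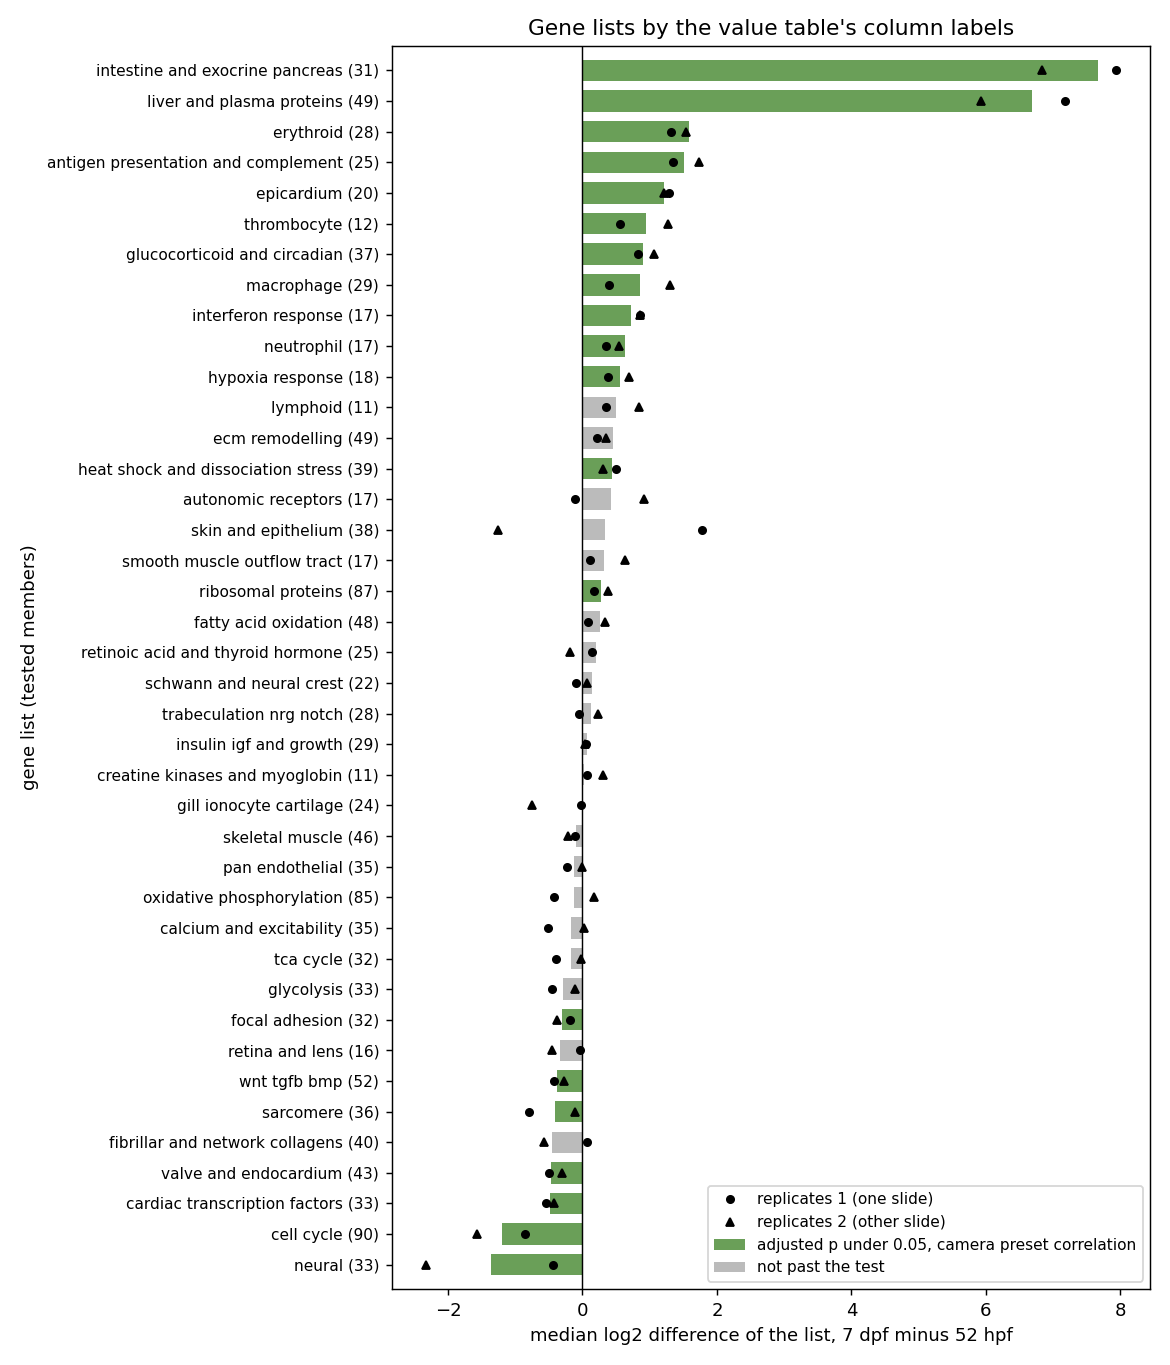
Median log2 difference, 7 dpf minus 52 hpf, of each of the 40 gene lists by the value table's column labels (bars), with the medians within each slide (circles and triangles) and the number of tested members in brackets. Green bars mark the 20 lists with a camera adjusted p under 0.05 at the preset correlation, none of which held with an estimated correlation, and the skin list differs most between the slides (1.78 and -1.26).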

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

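All alternatives by the value table's labels, and the crossed numbers, were chosen after seeing the data, and the others before the data were examined. By the scanner files' labels, 0 genes were called in either direction under every alternative except those named here. Without 7 dpf replicate 2 there were 143 higher genes (range 0 to 143 over the left-out arrays, with 0 lower in each), and with the authors' value table and its own labels 895 were higher and 628 lower. The 14 shifted lists became 0 with an estimated correlation, 20 with the value table, of which 6 were among the 14, and 8 to 25 when an array was left out. With normexp 14 were called, of which 8 were among the 14, and sarcomere, autonomic receptors, macrophage and retinoic acid and thyroid hormone lost their call (adjusted p = 0.339, 0.122, 0.0714 and 0.111). With crossed numbers as a block (52 hpf replicate 1 with 7 dpf replicate 2) 0 genes and 17 lists were called, and with the replicate block 0 genes and 14 lists. Between the 2 assignments the list medians turned to -1.20 for cell cycle, -1.36 for neural, -0.45 for collagens, -0.33 for retina and lens, -0.095 for skeletal muscle, -0.0095 for gill, ionocytes and cartilage, 0.42 for autonomic receptors, 0.28 for ribosomal proteins and 0.86 for macrophages, and myh6 to 1.23. After normexp the medians were -0.12 for skeletal muscle, -0.042 for retina and lens and -0.12 for retinoic acid and thyroid hormone, and the oxidative phosphorylation list (median -0.15) and the ribosomal list (-0.16) turned in camera, which compares with the other genes (median of all tested genes -0.19). When an array was left out, the difference ranged from -1.73 to 0.13 for myh6, from -0.86 to 0.023 for vmhc and from -1.38 to 0.41 for nppa. The list medians ranged from -0.69 to -0.060 for sarcomere, from -0.28 to 1.03 for cell cycle, from -0.73 to 0.19 for ribosomal proteins, from -0.87 to 0.22 for macrophages and from -2.07 to 4.44 for liver and plasma proteins. They ranged from -0.84 to -0.073 for autonomic receptors, from 0.074 to 0.65 for collagens, from -0.48 to -0.083 for oxidative phosphorylation, from -0.10 to 0.38 for skeletal muscle, from -0.032 to 2.63 for retina and lens, from 0.00039 to 0.90 for gill, ionocytes and cartilage and from 0.075 to 0.39 for retinoic acid and thyroid hormone. Each of these 12 lists lost or turned its call without at least 1 array. Collagens (adjusted p = 0.52) and retina and lens (0.0934) lost theirs without 7 dpf replicate 1 only.

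By the value table's labels, the counts of 895 higher and 628 lower genes were 91 and 2 with normexp and the 75th percentile changed together (1029 and 520 with that percentile alone), 497 and 155 with no filter on dim probes, 1468 and 1393 with a trended and robust variance, and 395 and 114 with the replicate block, which was also the slide as a block and gives no separate value. They were 553 and 518 with only probes well above background on all arrays. Leaving out 1 array gave 75 to 888 higher and 20 to 471 lower, with a lone sample assumed to vary like the pair of the other age. A left-out array leaves fewer samples, and for the others the cause was not tested. The 20 lists became 0 with an estimated correlation, and 16 to 23 otherwise, with no list turned. Leaving out 1 array ended 7 of the 20 calls, those of sarcomere, focal adhesion, ribosomal proteins, heat shock, hypoxia, neutrophil and Wnt, TGF-beta and BMP, with the lowest adjusted p at 0.0542 and the highest at 0.61. With the replicate block 18 of the 20 were called, all but focal adhesion and neutrophil. Of the named genes only myl7, not past the test, changed sign, to 0.047 with the 75th percentile and 0.11 with that percentile over probes detected on all arrays. Of the higher calls 336 rest on probes not well above background on either 52 hpf array.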

Other observations

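The tests of explanations, the splits of the arrays and the slide as a block were chosen after the results they concern were seen, while the comparison that gave the adjusted p-values of lft2 and ppp1r3b was planned. By the value table's labels the pools of 1 age differed most in skin genes. The 38 genes of the skin and epithelium list were higher in 52 hpf replicate 2 than in 52 hpf replicate 1 by a median of 3.63 on the log2 scale, and retina and lens genes by 1.69, gill, ionocyte and cartilage genes by 0.97 and neural genes by 0.87. In the same direction sarcomere genes differed by -0.82 and oxidative phosphorylation genes by -0.73. Between the 7 dpf replicates the skin list differed by -0.29, the neural list by -1.12, the liver list by -1.08 and the intestine and exocrine pancreas list by -1.43 (replicate 2 minus replicate 1). Among genes outside the lists, the left-right signalling gene lft2 differed between the ages by -4.93 ± 0.70 and the glycogen-targeting gene ppp1r3b by -4.33 ± 0.43 (limma adjusted p = 0.0351 and 0.0157). With the slide as a block lft2 was not called (adjusted p = 0.0709).

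The count of called genes depended on the deposited assignment used, and splitting the same scanner values into 2 pairs of arrays in each of the 3 possible ways gave 0 called genes by the scanner files' labels, 1549 by the value table's labels and 0 by slide, too few splits for a test against chance. A candidate explanation is that the scanner files were attached to the wrong samples, since over the probes of the heart lists the lowest correlation of pairs sharing an age by the value table exceeded the highest of all other pairs by 0.0388. Other tissue shared by pools of different age is argued against as the whole cause, since over 242 probes of heart muscle lists, outside the cell type lists, pairs sharing an age by the value table had correlations of 0.983 and 0.984 and those sharing one by the scanner files 0.9497 and 0.954 (gap 0.0293), while leaving out the cell type probes kept 45465 of 46023 and decided nothing. Exchanged ages in the value table stay open, because the intestine and exocrine pancreas list, at least 5.30 higher in the columns named 7 dpf in every setting, does not show which age those columns are. Likeness between pools does not show which record is right.

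Liver, intestine and exocrine pancreas genes were higher at 7 dpf by the value table's labels. Digestive organ tissue in the 7 dpf pools may be the source, and rises over 2-fold in 92.5% of the 80 tested members of both lists did not exclude it, but expression in heart cells could give the same share. The lists held 16 of 49 and 11 of 31 members well above background on both 52 hpf arrays. Scaling or background correction is argued against as the whole cause, since the median of neither list fell below 3.77 in any setting. Expression of such genes in heart cells with age was not tested and stays open.

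The cell cycle list was lower at 7 dpf by the value table's labels, and RNA of other tissue in the 7 dpf pools, which could lower all heart genes alike, stays open as a cause. The cell cycle median lay below the lowest of 4 heart lists by 0.0506 on 1 slide and 1.15 on the other, against a gap of 0.72 between the slides. Those 4 medians were -0.80 for sarcomere, -0.54 for cardiac transcription factors, -0.52 for calcium handling and -0.23 for endothelium on the first, and -0.11, -0.42, 0.02 and -0.00095 on the second. Dividing neural tissue in the 52 hpf pools is another candidate, and in 2 of 2 ages the pool with the higher neural median also had the higher cell cycle median, a weak test. A change in cycling with age stays open and untested.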
